A study of Strongylocentrotus purpuratus and Branchiostoma lanceolatum and Danio rerio with 15 samples.

How the data were processed

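ACE-seq libraries of genomic DNA were analysed from 8 sea urchin, 6 lancelet and 1 zebrafish samples. Per the labels, DNA was spiked with CpG-methylated lambda DNA and with pUC19 plasmid DNA hydroxymethylated at every cytosine, treated with a glucosyltransferase that protects hydroxymethylcytosine, and then with the deaminase APOBEC3A, which acts on cytosine and methylcytosine. The submitters' processing notes name Trimmomatic, Picard and MethylDackel as tools and danRer10 and mm10 as genome builds. Tool versions and the aligner are not given in the sources used here. The deposited files give, for each CpG, counts of reads with C (protected) and of reads with T (deaminated), with both strands merged. The deposited files also give a percent, which was the whole-number part of protected counts over all counts in every line and was used only to check the columns. The sea urchin and lancelet files hold CpGs with at least 10 counts and passed a read filter whose nature is not given in the sources used here. The zebrafish file has no such minimum, holds CpGs from 1 count on, and shows no read filter.

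Replicate numbers and groups came from the labels. The names of the 36 hpf and liver files carry another build name than the other lancelet files, but 83.6% and 84.2% of their CpGs lay at CpG positions of the larva replicate 1 file and 0% did after a shift of 1 bp, so that all 6 lancelet files were compared by position. The zebrafish file name says mm10, while its chromosomes are numbered 1 to 25 as in zebrafish, and danRer10 was taken as its build. Spike-in and mitochondrial sequences were set apart from the genome.

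The level of a library was the protected share of all counts, in percent, over CpGs with a coverage of at least 10 in every library of the comparison: 1259501 CpGs for the 8 sea urchin libraries, 3712502 for the larva and juvenile libraries and 2904119 for all 6 lancelet libraries. Sea urchin stages were compared by an exact permutation test of the between-group sum of squares over all 105 partitions into 4 groups of 2, and larvae with juveniles by an exact two-sided permutation test. Single libraries have 95% Wilson intervals.

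Windows of 5 kb with at least 5 shared CpGs were tested with edgeR 4.0.16 in R 4.3.3. The design had 1 coefficient per library for its total and 1 per group for the protected counts, with quasi-likelihood tests, the same library size for protected and deaminated counts, and Benjamini-Hochberg adjusted p under 0.05 (two-sided). The 8 sea urchin libraries shared 1 fit for 5 contrasts, and the 2 larva and 2 juvenile libraries had their own. In the scaled form, protected and deaminated counts had separate library sizes, so that a change was read relative to the library's genome-wide level. limma 3.58.1 tested log2 ratios of protected to deaminated counts with a pseudocount of 0.5. Both forms were tested on simulated data with 200 changed windows at folds of 2, 3, 4 and 6. The changed windows came from a limited range of levels and were raised in juveniles or tube feet. Recovery outside that range and of lowered windows was not simulated. In simulated lancelet libraries the unscaled form recovered 0%, 18%, 44% and 80% of them and the scaled form 4%, 36%, 60% and 90%, with 0 false calls. In simulated sea urchin libraries the unscaled form recovered 0% at each fold and the scaled form 0%, 22%, 36% and 72%, with 1 false call. The simulated libraries had estimated dispersions of 0.0218 and 0.0151 (lancelet, unscaled and scaled) and 0.186 and 0.0157 (sea urchin), below those of the real ones, 0.0311 and 0.0212 and 0.265 and 0.0614.

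The windows named were set by a rule: for each contrast with called windows, those with the largest difference in percentage points among windows past the threshold in which both libraries of 1 group lay on the same side of both libraries of the other, up to 10 per direction, with the first 3 given in full. For each species the 5 windows of at least 20 shared CpGs with the highest mean level were also named. Sc0000154 was singled out for its adjusted p after its values were seen. Limits given beside shares of 0 use 3 counts over the summed counts of the group's 2 libraries.

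CpGs above background were called per library by a one-sided exact binomial test against the lambda rate, the background of methylated CpGs. Benjamini-Hochberg adjusted p had to be under 0.05. On simulated data this recovered 69.7% of CpGs at a level of 30%, and 2.04% of calls were false. Lambda CpGs, thinned to the depths of the genome's CpGs or kept at their own depth where that was lower, were called in the same way. Runs of 20 adjacent lambda CpGs gave the range of background in units like a window. Window levels were correlated between all pairs of libraries of a species.

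These comparisons, tests and most alternatives were chosen before the data were examined. Alternatives were the window size (2 kb and 20 kb), a coverage minimum of 20, at least 20 CpGs per window, CpGs above 3 times the median coverage left out, the scaled form, limma, a replicate block, each replicate left out in turn, the lambda rate subtracted, unweighted levels, each library's own CpGs, and for single CpGs an adjusted p under 0.01, thinning to 10 counts, a doubled background and a fixed level of 20%. Scaling to the lambda rate, leaving out both libraries with a lambda rate of 5% or more, and alternatives to the scaled window tests were chosen after seeing the data. Strand symmetry was left out because the files merge both strands, and gene features were left out because no annotation of the files' sea urchin and lancelet builds was used here. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the other steps.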

Results

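Hydroxymethylation of CpG cytosines was mapped by ACE-seq in purple sea urchin, European lancelet and zebrafish. In this assay hydroxymethylcytosine is shielded by a glucose group, while cytosine and methylcytosine are converted by a deaminase, so that a read C at a CpG counts as protected and a read T as deaminated. The 15 libraries fall into 9 groups. Sea urchin embryos of 24, 48 and 72 hours post fertilisation (hpf) and adult tube feet, the hydraulic appendages of the animal, were each measured in 2 libraries, as were lancelet larvae (60 to 70 hpf) and juveniles (3 to 4 months). Lancelet embryos of 36 hpf, lancelet adult liver and zebrafish embryos of 24 hpf each have 1 library, and their values carry no replicate error. The series describes the replicates as biological. Whether they came from separate spawnings or animals is not stated, so that each p measures the spread between these libraries. Genome CpGs with a coverage of at least 10 held 52297191 to 57760289 counts in the sea urchin replicate 1 libraries and 140368370 to 163724657 in the replicate 2 libraries. The lancelet libraries held 102170587 to 173017546 counts and the zebrafish library 49259886, and median coverage per CpG ran from 12 to 23 across all 15 libraries. Each sample also carried CpG-methylated lambda DNA. The share of lambda CpGs read as protected, called the lambda rate here, is the background left by incomplete deamination of methylated CpGs. The background of unmethylated CpGs was not measured and may be lower. Over its own CpGs, each library had a level of 0.283 to 0.581 times its lambda rate. A level below the lambda rate therefore need not be background alone.

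The first question was how much protected CpG each sea urchin stage carries. Over the 1259501 CpGs covered in all 8 libraries, the protected level was 0.872% ± 0.130 (SD, n = 2) at 24 hpf and 1.28% ± 0.805 (SD, n = 2) at 48 hpf. It was 1.89% ± 1.58 (SD, n = 2) at 72 hpf and 0.948% ± 0.0546 (SD, n = 2) in tube feet. Among replicate 2 libraries, the 24, 48 and 72 hpf embryos had 0.781%, 0.710% and 0.770% and tube feet 0.987%. The stages did not differ by more than the replicates did, with p = 0.933 in an exact permutation test over 105 partitions of the 8 libraries (one-sided by construction). Replicate 1 had 2.60 times the level of replicate 2 at 48 hpf and 3.91 times at 72 hpf, and the lambda rates of those replicate 1 libraries were 5.01% and 8.40%, against 1.54% to 2.55% in the other 6 sea urchin libraries. Across the 8 libraries the level followed the lambda rate, with Pearson's r = 0.993 (exact permutation p = 0.00216) and Spearman's rho = 0.833 (exact permutation p = 0.0154). Without the 2 libraries farthest in lambda rate, r was 0.562 (exact permutation p = 0.239) and rho 0.60 (exact permutation p = 0.242), so that the relation rests on these libraries. Divided by the lambda rate, the level was 0.383 ± 0.00737 (SD, n = 2) at 24 hpf, 0.414 ± 0.0647 (SD, n = 2) at 48 hpf, 0.416 ± 0.0807 (SD, n = 2) at 72 hpf and 0.519 ± 0.0723 (SD, n = 2) in tube feet, with p = 0.390 in the same exact permutation test.

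**Figure D1:**
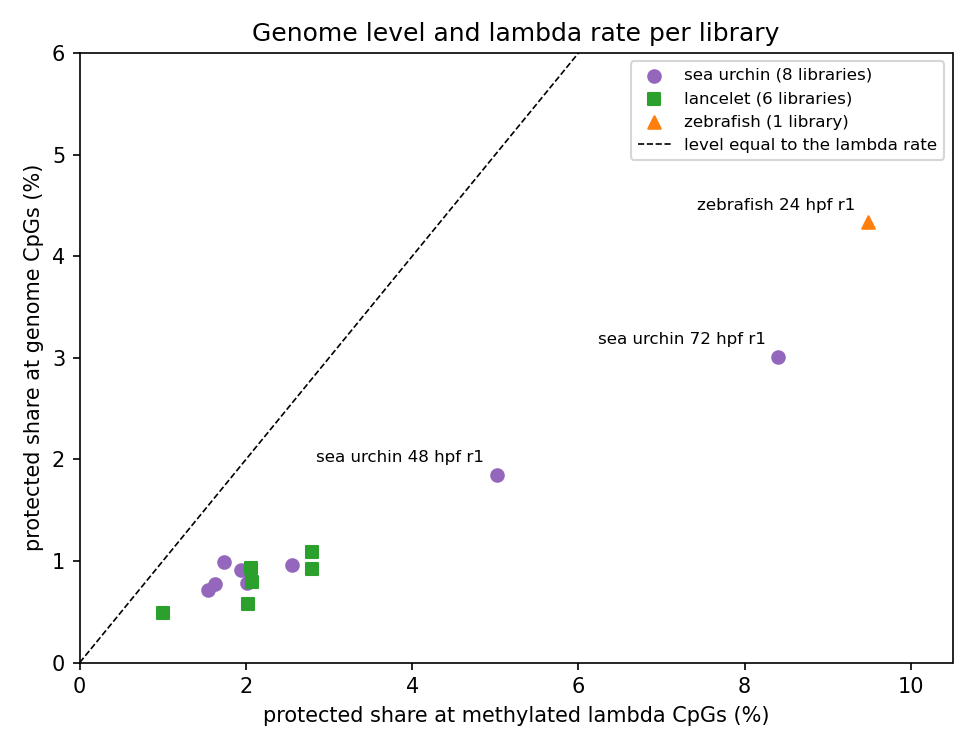
Each point is 1 of the 15 libraries, with the share of protected counts at lambda CpGs on the x axis and at genome CpGs on the y axis, both in percent; the dashed line marks equal values. All 15 libraries lie below the line, and the 48 and 72 hpf sea urchin replicate 1 libraries stand apart from the other 6 sea urchin libraries at lambda rates of 5.01% and 8.40%.

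The next question was where sea urchin embryos change between stages, tested in 5-kb windows. Scaffold1341 from 75001 to 80000 had the highest mean level over the 8 libraries, with 22.4% to 46.1% per library over 30 CpGs (mean 29.9% ± 7.36, SD across the 8 libraries). Scaffold895 from 30001 to 35000 followed at 25.7% ± 3.54, Scaffold2080 from 115001 to 120000 at 24.5% ± 10.0, Scaffold30 from 670001 to 675000 at 21.9% ± 4.31 and Scaffold374 from 130001 to 135000 at 21.8% ± 12.9. The order rests partly on the replicate 1 libraries with high lambda rates: Scaffold2080 and Scaffold374 had 43.2% and 44.8% in 72 hpf replicate 1 and 18.5% and 8.38% in 72 hpf replicate 2. Most windows were near 0, with library medians from 0.142% to 0.718% among windows of at least 20 CpGs. Of 52061 windows tested with edgeR, 0 differed in level between 48 and 24 hpf, between 72 and 48 hpf or between 72 and 24 hpf. Unadjusted p was under 0.05 in 90, 148 and 396 of them, and limma called 0, 0 and 0. The edgeR test scaled to each library's genome-wide level also called 0, 0 and 0, with 787, 702 and 1055 windows at an unadjusted p under 0.05. The scaling moved the median log2 change over all windows from 0.35 to 0.03 for 48 against 24 hpf, from 0.57 to 0.16 for 72 against 48 hpf and from 1.07 to 0.24 for 72 against 24 hpf. In simulated sea urchin libraries with the background of the real ones, the unscaled test recovered 0% of windows raised 6-fold in tube feet and the scaled test 72%. The simulated libraries varied less than the real ones, with an estimated dispersion of 0.0157 against 0.0614 in the scaled test, so that 72% does not carry over to the real scaled test, and the unscaled counts of 0 set no limit on change.

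In the scaled test a set of windows had lower levels in tube feet than at 72 hpf, though whether protection depends on the stage stays open. Scaled to each library's genome-wide level, 42 windows on 39 scaffolds were lower in tube feet than at 72 hpf, with a median level of 0.110% in tube feet and 14.4% at 72 hpf, and 1 window was higher. These 42 windows also had median levels of 11.9% and 7.83% in the 48 hpf libraries (lambda rates 5.01% and 1.54%). In the 24 hpf libraries the medians were 3.12% and 2.22%, near the lambda rates of 2.55% and 2.01%. Scaffold131 from 870001 to 875000 held 22 shared CpGs and had 0.325% ± 0.0963 (SD, n = 2) in tube feet and 24.1% ± 6.95 (SD, n = 2) at 72 hpf (edgeR adjusted p = 2.46e-11). Scaffold41 from 80001 to 85000 held 5 CpGs and had 0 protected counts in tube feet, which allows a share of up to 1.29%, against 22.2% ± 8.72 (SD, n = 2) at 72 hpf (edgeR adjusted p = 0.0274). Scaffold71 from 520001 to 525000 held 6 CpGs and had 0.602% ± 0.852 (SD, n = 2) and 20.5% ± 0.965 (SD, n = 2) (edgeR adjusted p = 0.0293). The window that was higher, Scaffold29934 from 1 to 5000, held 7 CpGs and had 49.9% ± 20.4 (SD, n = 2) in tube feet and 19.2% ± 2.20 (SD, n = 2) at 72 hpf (edgeR adjusted p = 0.0390). In all 42 lower windows both 72 hpf libraries lay above both tube feet libraries, which the choice of windows on these same libraries favours. In 31 both 72 hpf libraries exceeded their own lambda rates, and in 11 the 72 hpf mean lay below the mean lambda rate of these libraries. The scaled form was the second choice of test. The unscaled edgeR test called 0 windows, with 749 at an unadjusted p under 0.05, and limma without scaling called 55 (1 higher, 54 lower). The scaling moved the median log2 change over all windows from -0.97 to -0.28, and scaling to the lambda rate moved it to 0.02. The scaled count was 13 (3 higher, 10 lower) without the 72 hpf replicate 2 library, 9 (3 higher, 6 lower) without the tube feet replicate 2 library and 14 (0 higher, 14 lower) with scaling to the lambda rate. Without both libraries of a lambda rate over 5%, which leaves 72 hpf a single library, it was 38 (2 higher, 36 lower).

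**Figure D2:**
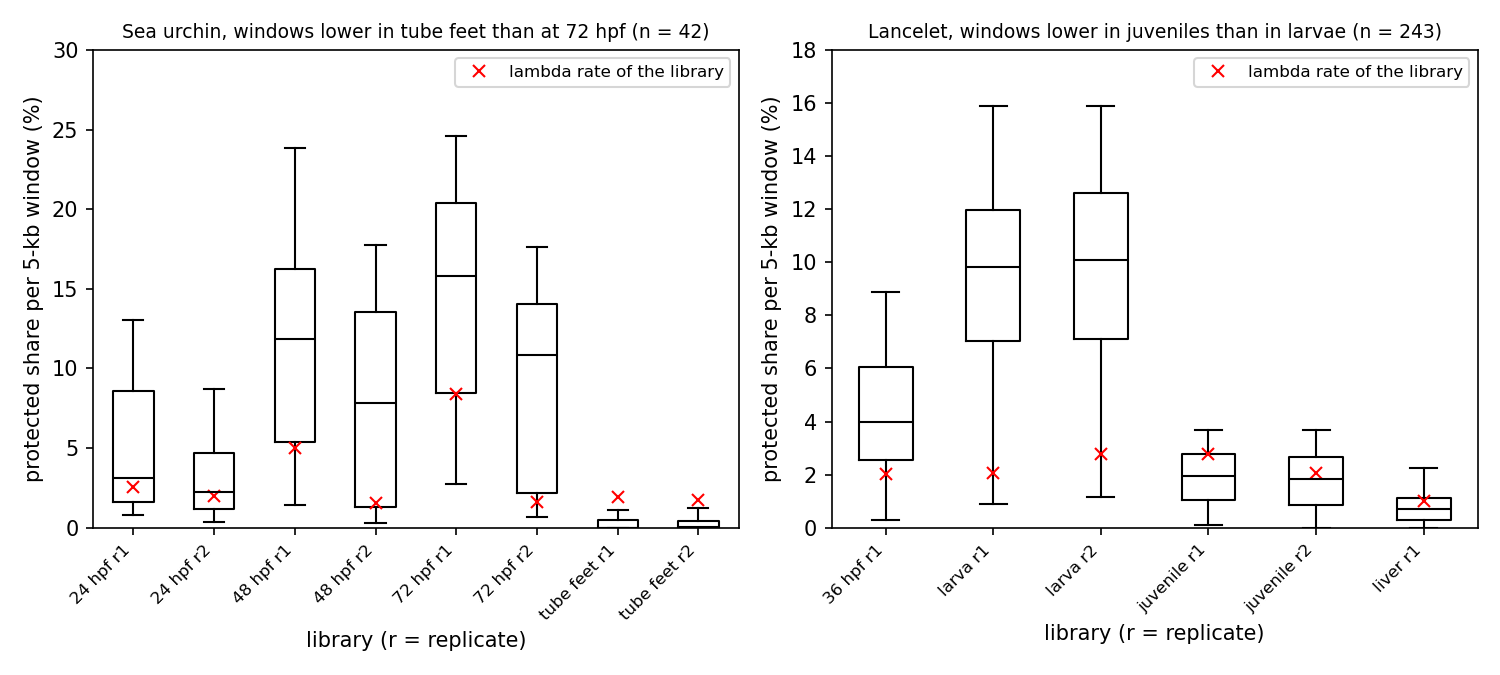
Boxes show the protected share in percent per 5-kb window for each library (line, median; box, quartiles; whiskers, the percentiles from 5 to 95), in the 42 sea urchin windows lower in tube feet than at 72 hpf and in the 243 lancelet windows lower in juveniles than in larvae; crosses mark each library's lambda rate. The sea urchin windows were chosen on the contrast of 72 hpf with tube feet and the lancelet windows on that of larvae with juveniles, and the 24, 48 and 36 hpf and liver libraries lie outside these contrasts.

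Against 24 hpf embryos, 16 windows were lower in tube feet and 3 were higher in the same scaled edgeR test. The 16 lower windows had a median level of 0.304% in tube feet and 10.4% at 24 hpf, and their 72 hpf medians were 14.9% and 10.4%. Scaffold2377 from 55001 to 60000 (7 CpGs) had 2.15% ± 1.38 (SD, n = 2) in tube feet and 23.0% ± 4.90 (SD, n = 2) at 24 hpf (edgeR adjusted p = 0.0227). Scaffold1275 from 85001 to 90000 (6 CpGs) had 0.526% ± 0.744 (SD, n = 2) and 21.7% ± 8.81 (SD, n = 2) (edgeR adjusted p = 0.00258). Scaffold219 from 190001 to 195000 (7 CpGs) had 0.282% ± 0.399 (SD, n = 2) and 20.2% ± 15.9 (SD, n = 2) (edgeR adjusted p = 1.76e-05). The 3 higher windows were Scaffold3347 from 10001 to 15000, with 8.83% ± 1.27 (SD, n = 2) in tube feet and 0.944% ± 0.718 (SD, n = 2) at 24 hpf, Scaffold92 from 340001 to 345000, with 7.12% ± 0.695 (SD, n = 2) and 0.651% ± 0.0506 (SD, n = 2), and Scaffold2320 from 125001 to 130000, with 6.21% ± 1.05 (SD, n = 2) and 0.784% ± 0.798 (SD, n = 2). Their edgeR adjusted p values were 0.0165, 0.0109 and 0.0313. The unscaled edgeR test called 0 windows, with 251 at an unadjusted p under 0.05, and limma without scaling called 9, all lower in tube feet. The split depended on the scaling and on the test, with 13 higher and 9 lower after scaling to the lambda rate, where the median log2 change was 0.25 against 0.04 unscaled, and with 29 higher and 30 lower in scaled limma. The scaled edgeR count of 19 was 9 without 24 hpf replicate 1, 12 without 24 hpf replicate 2, 32 without tube feet replicate 1 and 7 without tube feet replicate 2.

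In the lancelet, larvae carried protected regions that juveniles largely lacked. Of 68332 windows, 243 on 142 scaffolds were lower in juveniles and 11 were higher, and the 243 had a median level of 10.1% in larvae and 1.95% in juveniles. The median difference in these 243 windows was 7.78 percentage points, within a range from 0.256 to 18.1. The genome as a whole differed less, with 1.02% ± 0.121 (SD, n = 2) in larvae and 0.869% ± 0.0995 (SD, n = 2) in juveniles over 3712502 shared CpGs. That difference of -0.152 percentage points had p = 0.667 in an exact two-sided permutation test, for which 2 libraries against 2 allow no p below 0.333.

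The window xfSc0004190 from 1 to 5000 showed the largest difference, with 19.5% ± 0.0719 (SD, n = 2) in larvae and 1.35% ± 0.279 (SD, n = 2) in juveniles over 10 CpGs (edgeR adjusted p = 1.48e-04). Sc0000037 from 1175001 to 1180000 had 17.1% ± 4.04 (SD, n = 2) in larvae and 0 protected counts in juveniles over 7 CpGs, which allows a share of up to 1.63% (edgeR adjusted p = 0.00557). Sc0000040 from 185001 to 190000 had 17.1% ± 2.31 (SD, n = 2) and 1.08% ± 1.09 (SD, n = 2) over 20 CpGs (edgeR adjusted p = 4.33e-05). Sc0000154 from 550001 to 555000, with 15.0% ± 1.83 (SD, n = 2) and 1.12% ± 0.289 (SD, n = 2) over 45 CpGs, had the smallest adjusted p of all windows (edgeR, 4.51e-10). In all 243 windows both larva libraries lay above both juvenile libraries, which the choice of windows on these same libraries favours. In 214 both larva libraries exceeded their own lambda rates. The 11 windows that were higher in juveniles stayed at low levels, with a median of 1.11% in juveniles and 0.0934% in larvae, and in 9 of them the juvenile mean lay below the lambda rate. They included xpSc0039671 from 505001 to 510000, with 2.86% ± 1.38 (SD, n = 2) in juveniles and 0.192% ± 0.173 (SD, n = 2) in larvae (edgeR adjusted p = 2.72e-04), and xpSc0039787 from 10001 to 15000, with 2.73% ± 0.744 (SD, n = 2) and 0.853% ± 0.171 (SD, n = 2) (edgeR adjusted p = 0.0362). The third was Sc0000013 from 1280001 to 1285000, with 1.41% ± 0.109 (SD, n = 2) in juveniles and 0 protected counts in larvae, which allows a share of up to 0.208% (edgeR adjusted p = 0.0352).

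**Figure D3:**
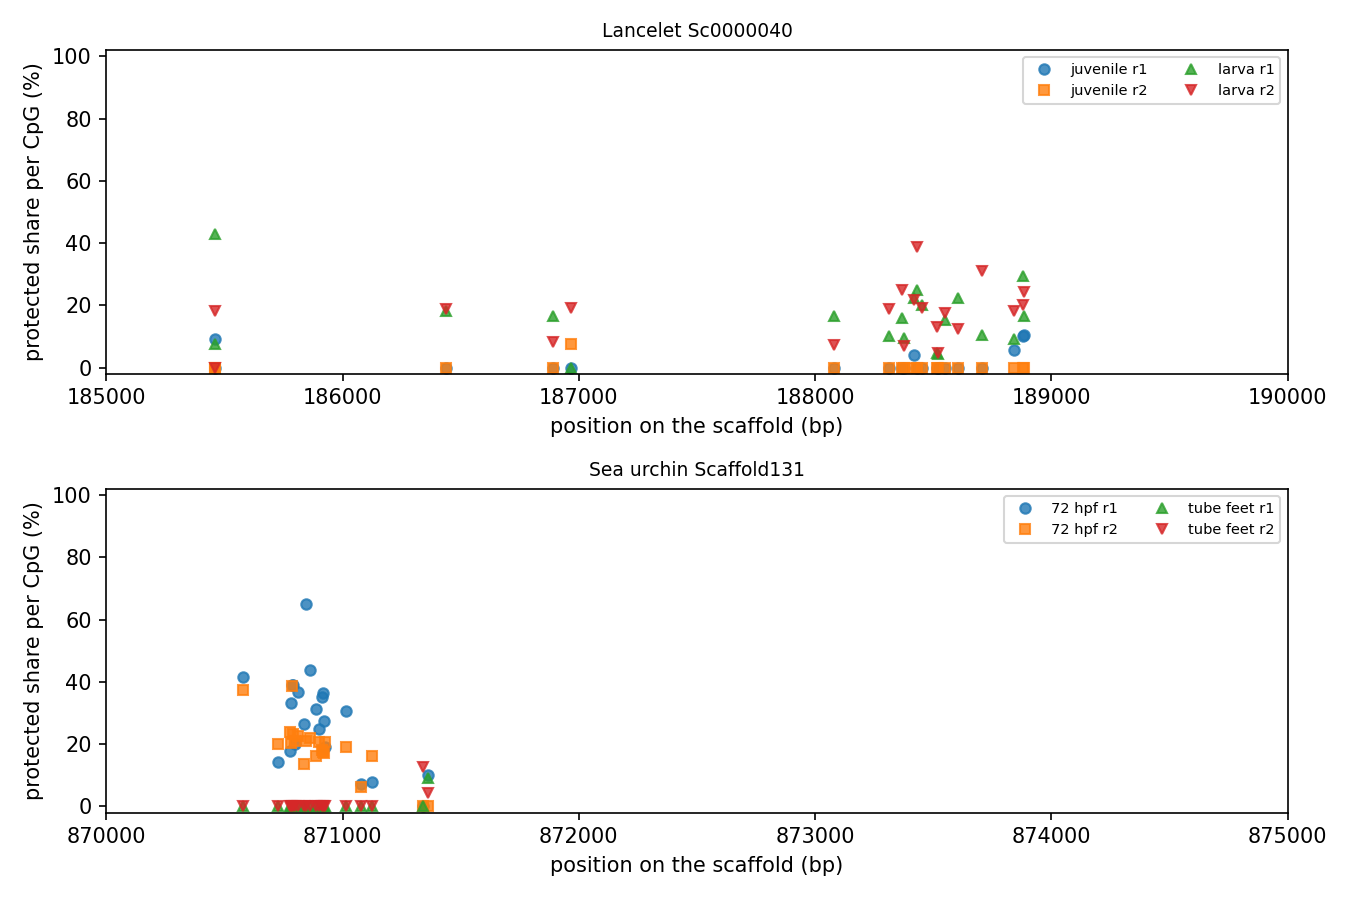
Each point is 1 CpG shared by the libraries in a 5-kb window, with its position in bp on the x axis and its protected share in percent on the y axis, for the lancelet window on Sc0000040 and the sea urchin window on Scaffold131. The larva and 72 hpf libraries have raised shares at many CpGs of the window, while most juvenile and tube feet points lie at 0%.

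The median log2 change over all lancelet windows was -0.16 without scaling and 0.08 with scaling to the genome-wide level. The scaled edgeR test called 445 windows (77 higher and 368 lower in juveniles), and limma without scaling called 239 (5 higher, 234 lower). With the replicate number as a block the unscaled count was 59 (2 higher, 57 lower), and it was 3 without larva replicate 1, 1 without larva replicate 2, 92 without juvenile replicate 1 and 65 without juvenile replicate 2. Scaled limma called 0 windows, with a smallest adjusted p of 0.0578 and 5412 windows at an unadjusted p under 0.05.

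The 36 hpf embryo and the adult liver extend the lancelet stages, as single libraries. In the windows lower in juveniles than in larvae, the 36 hpf library had a median level of 3.97% and lay above the juvenile mean in 217 of 242 windows. The liver library had a median of 0.694% in these windows and lay above the juvenile mean in 27 of 237. Its lambda rate was 1.01%, against 2.79% and 2.07% in the juvenile libraries, so that its lower levels need not be a further loss. The windows were chosen for low juvenile levels, which by itself raises the count of other libraries above the juvenile mean. The window xfSc0004190 from 1 to 5000 had 9.69% at 36 hpf and 0.483% in liver, and Sc0000040 from 185001 to 190000 had 7.43% at 36 hpf and 0 protected counts in liver. Over its own CpGs the 36 hpf library had a level of 0.575% (95% Wilson interval 0.574% to 0.576%) and the liver library 0.491% (0.490% to 0.493%), with lambda rates of 2.03% and 1.01%. Such intervals, here and elsewhere, and limits from counts of 0 cover counting error only, and they treat each count as independent. A read can cover several neighbouring CpGs, so that they may be too narrow even for counting error.

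A few lancelet windows stayed protected in all 6 libraries. Sc0000058 from 360001 to 365000 led with levels from 16.7% to 27.5% over 20 CpGs (mean 22.5% ± 4.64, SD across the 6 libraries). Sc0000056 from 310001 to 315000 had 19.6% ± 4.97, xfSc0003827 from 1 to 5000 had 17.9% ± 3.87, Sc0000012 from 2690001 to 2695000 had 14.7% ± 2.02 and Sc0000067 from 1165001 to 1170000 had 14.7% ± 4.56. Of 43715 windows with at least 20 shared CpGs, 19 exceeded in all 6 libraries the highest level that any run of 20 adjacent lambda CpGs reached in the same library. Both larva libraries exceeded it in 238 windows and both juvenile libraries in 34. In the sea urchin 35 of 21524 windows exceeded it in all 8 libraries, with 125, 124 and 126 for both libraries of the 24, 48 and 72 hpf embryos and 66 for both tube feet libraries. These counts are not on the same footing, since the highest run had 5.60% in 24 hpf replicate 1, where there were 9 runs, and 10.9% in tube feet replicate 1, where there were 80.

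Single CpGs above background recurred between libraries. At an adjusted binomial p under 0.05 against the library's lambda rate, 3801 sea urchin CpGs were called in both 24 hpf libraries, 4548 in both 48 hpf libraries, 3791 in both 72 hpf libraries and 3821 in both tube feet libraries. Independent calls would have given 40.5, 65.6, 61.2 and 63.2. All 8 sea urchin libraries called 1496 CpGs, and all 6 lancelet libraries called 1505. Larvae shared 8287 called CpGs between replicates and juveniles 4117, where independent calls would have given 107 and 23.8. As a share of the CpGs called in either library, the overlap was 32.8% between the juvenile libraries and 30.6% between the larva libraries, and at most 27.7% between lancelet libraries of different stages. In the sea urchin it was at most 35.9% within a stage and up to 42.0% between stages, in the 48 and 72 hpf replicate 2 libraries. The called share of shared CpGs was 0.487% to 1.03% in the sea urchin libraries and 0.202% to 0.646% in the lancelet libraries. Lambda CpGs thinned to the genome's depths were called in 0.380% to 1.21% of cases in the 13 invertebrate libraries other than liver, each above the share of all genome CpGs called in the same library, and in 0.129% in liver, where 0.180% of genome CpGs were called. This order did not hold in every setting: at a coverage of at least 20, the share of genome CpGs called was 1.43 to 2.13 times the lambda share in the 4 sea urchin replicate 1 libraries. With CpGs thinned to 10 counts it was 1.07 and 1.10 times in the 48 and 72 hpf replicate 2 libraries. At an adjusted p under 0.01 it was 1.56 and 1.07 times in tube feet and 72 hpf replicate 1, and no lambda CpG was called in 24 and 48 hpf replicate 1. With a doubled background it was 1.94, 1.27 and 1.06 times in 72 hpf replicate 1, tube feet replicate 1 and 72 hpf replicate 2, and in 24 and 48 hpf replicate 1 no lambda CpG was called. In the 4 sea urchin replicate 1 libraries and liver, lambda CpGs had a mean coverage of only 11.3 to 15.1 and could not match deeper genome CpGs. Genome CpGs there had more power to be called, so that the order in these libraries cannot be read. Lambda rates per CpG also recurred, with a mean r of 0.974 between 8 deeply covered libraries across 3109 lambda CpGs, which are not independent replicates, so that recurrence alone does not separate protected CpGs from CpGs of raised background.

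Levels of windows repeated between libraries of a species. Across 56556 sea urchin windows, Pearson's r between libraries of the same stage averaged 0.760 (4 pairs), 0.738 between libraries of another stage and the same replicate number (12 pairs) and 0.718 between libraries that differ in both (12 pairs). Spearman's rho averaged 0.732, 0.731 and 0.725 in the same order, so that by rank the same-stage pairs hardly stood apart. At a coverage of at least 20 the averages of r were 0.816, 0.833 and 0.812. Libraries of a stage were then no more alike than libraries of a replicate number. Across 65875 lancelet windows, the pairs of larva and juvenile replicates averaged 0.845 and the 13 pairs of different stages 0.720. These correlations are across windows, which are not independent replicates, and carry no test.

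Zebrafish embryos of 24 hpf had the highest protected level of the 15 libraries, with 4.33% (95% Wilson interval 4.33% to 4.34%) over 3622929 CpGs, and also the highest lambda rate, 9.49%. The level varied little between chromosomes, from 3.98% on chromosome 4 to 4.62% on chromosome 13, and the mitochondrial genome had 1.00%. The most protected window lay on chromosome 17 from 20780001 to 20785000, with 42.7% (36.4% to 49.3%) over 20 CpGs. Chromosome 2 from 35320001 to 35325000 had 39.3% (35.1% to 43.8%), chromosome 8 from 46025001 to 46030000 had 38.3% (34.1% to 42.7%), chromosome 7 from 12220001 to 12225000 had 29.5% (25.8% to 33.5%) and chromosome 15 from 47470001 to 47475000 had 29.2% (25.3% to 33.5%). They were among 9 of 68253 windows above 26.7%, the highest level of a run of 20 lambda CpGs in the library. The median zebrafish window had 3.88%, and only 1.62% of windows were under 0.5%, whereas 42.3% to 66.5% of windows were under 0.5% in the invertebrate libraries. Zebrafish is a single library with a high lambda rate, and only its file shows no read filter, so that the contrast need not be one between species. At single CpGs, 663 (0.0183%) were called above the lambda rate.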

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

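All tests in this part were chosen after the results were seen. The lancelet and sea urchin groups hold at most 2 libraries each, too few for a search for single libraries that stand apart.

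The hydroxymethylated pUC19 spike-in, which no comparison used, was protected above the lambda rate of its library in 9 libraries. In sea urchin replicate 2 the pUC19 rate was 3.31% at 24 hpf, 2.70% at 48 hpf, 2.77% at 72 hpf and 3.11% in tube feet. It was 3.59% and 4.49% in the larva libraries and 4.20% and 3.47% in the juvenile libraries (replicates 1 and 2), and 90.0% in zebrafish. The liver library, the only other with listed pUC19 CpGs, had 0.690%, below its lambda rate of 1.01%.

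A pUC19 rate near the lambda rate in 8 invertebrate libraries, where full protection was the aim of the spike-in, was weighed against a pair of technical explanations. Failed protection could give it, and so could a read filter that removes reads with many unconverted cytosines, since the sea urchin and lancelet files name a filter step and the zebrafish file does not. Liver was the only invertebrate library with listed pUC19 CpGs and a spike-in depth far from the cap near 2000 counts. Its pUC19 coverage was 0.741 times the lambda coverage, over 13 of 110 pUC19 CpGs and 1783 lambda CpGs. CpGs under 10 counts are not listed there, so that 0.741 may be too high. The zebrafish library, which has no such minimum, had 56.9 times and a rate of 90.0%, so that these ratios are not on the same footing. The shallow sea urchin libraries and the lancelet embryo library listed 180 to 2112 lambda CpGs but no pUC19 CpG. Whether pUC19 reads were lost there was not tested. Both explanations stay open and cannot be told apart, because filter and species coincide and the depth of the deeply covered spike-ins is capped. No biological explanation applies to a spike-in. If protection failed, levels in the invertebrate genomes may be too low by an unknown factor. A filter could lower them only through genome reads with many unconverted cytosines, by an amount that is not known. The values of 0.741 and 90.0% leave this undecided.

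The sea urchin level was 2.60 times higher in replicate 1 than in replicate 2 at 48 hpf and 3.91 times at 72 hpf. Shallower sequencing of replicate 1 alone is argued against, since replicate 1 was as shallow at 24 hpf and in tube feet, where the highest ratio was 1.24. Undeaminated cytosine is a candidate explanation: after division by the lambda rate the ratio farther from 1 was 0.759, at 72 hpf. A difference between the animals or spawnings behind the replicates was not tested and stays open.

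For windows higher at 72 hpf or in larvae than later, undeaminated cytosine was weighed by the lambda rate, which measures methylated CpGs only. It is argued against in the lancelet, with larvae at 0.998 times the lambda rate of juveniles. It is also argued against in sea urchin replicate 2, with 72 hpf embryos at 0.941 times the lambda rate of tube feet. For the size of the difference in sea urchin replicate 1, where the rates were 8.40% and 1.95%, it stays open. A gain of methylation alone stays open in both species. Both libraries of the higher group exceeded the highest run of 20 lambda CpGs in 123 of 243 lancelet and 19 of 42 sea urchin windows. That cannot exclude it, since windows could hold as few as 5 CpGs and at most 155 runs per library stood against 68332 and 52061 windows. Single variable sites are argued against because the largest CpG gave a median of 8.38% of the gain in the 243 lancelet windows and 14.6% in the 42 sea urchin windows. Extra DNA copies or foreign reads are argued against for the lancelet windows as a set, where the log2 ratio of relative coverage minus the least that added protected reads would need had a median of -0.107 (quartiles -0.224 and -0.00503; 60 of 243 windows at 0 or above), and stay open for the sea urchin (median -0.0429, quartiles -0.400 and 0.0549). Windows chosen on replicate 1 by scaled level had larvae above juveniles in replicate 2 in 216 of 243 (226 with the replicates swapped), against 104 (105 swapped) when chosen for the opposite difference, while in the sea urchin 72 hpf was above tube feet in 32 of 42 (36 swapped), against 34 (9 swapped), so that the sea urchin test separates the choices only when swapped. The lancelet values are consistent with protection that depends on the stage, as a hypothesis; for the sea urchin this stays open, and a change in cell composition between embryos, larvae, juveniles and tube feet was not tested.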

How the results depend on the processing

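Leaving out both libraries with a lambda rate of 5% or more, scaling or division by the lambda rate, and alternatives to the scaled window tests were chosen after seeing the data; the others were planned. No main test result reversed its direction, but sea urchin level differences within the replicate spread did: 72 hpf to tube feet went from -0.943 to 2.23 and 24 to 72 hpf from 1.02 to -1.72 percentage points with the lambda rate subtracted. Among the main results, 123 alternatives kept the side of the threshold or moved within the stated bounds, 9 brought a count of 0 above 0 and 12 moved a value further. The sea urchin level test stayed above 0.05 in every alternative run, with 0.833 under the replicate block, 0.333 without both high-background libraries and 0.133 to 0.971 with each library left out; the lancelet difference ran from -0.238 to -0.0667 with each library left out. Sea urchin window counts were 0 in 81 of 90 alternatives to the unscaled edgeR test, replicate block and each library left out included (0 to 0 in each contrast), which shows no stability where the test stayed unscaled, as it recovered 0% of simulated 6-fold changes. For tube feet against 24 hpf the others were 19 scaled to the genome-wide level, 9 by limma, 22 scaled to the lambda rate and 6 without both high-background libraries; for tube feet against 72 hpf they were 43, 55, 14 and 8, with 72 hpf left as a lone library in the last, assumed to vary like the other groups; 72 against 24 hpf had 1 scaled to the lambda rate. With each library left out, the scaled tests called 0 to 0 windows for 48 against 24 hpf, 0 to 1 for 72 against 48 hpf, 0 to 2 for 72 against 24 hpf, 7 to 32 for tube feet against 24 hpf and 9 to 44 for tube feet against 72 hpf; with the replicate block they called 23 and 50 for the tube feet contrasts. The 254 lancelet windows became 445 scaled to the genome-wide level, 476 scaled to the lambda rate, 59 with the replicate block and 1 to 92 with each library left out, which leaves fewer libraries; the scaled count ran from 118 to 350. CpGs called in all 8 sea urchin libraries fell from 1496 to 98 when thinned to 10 counts, which lowers power by construction, and to 558 with a doubled background; those in all 6 lancelet libraries fell from 1505 to 69 and 622. The gap in window correlation between same-stage sea urchin pairs and pairs differing in stage and replicate number went from 0.0422 to 0.00359 at a coverage minimum of 20. Except where stated, the cause was not tested. Replicate numbers did not pair the libraries in every comparison: same-numbered libraries deviated together among sea urchin embryos (0.181 to 0.469), but not between embryos and tube feet (-0.0838 to 0.0821) or in the lancelet (-0.0811). Same-numbered 48 and 72 hpf libraries correlated at 0.846 and 0.847, above the same-stage pairs (at most 0.786), so a shared origin of these embryos stays open. The alternatives listed for strand symmetry (a coverage minimum of 20) and for promoters (2 kb upstream) were not run, because those results were left out.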

Other observations

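The tests and values of this part were chosen after the results were seen.

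Protected counts were unevenly spread over the invertebrate genomes. The windows above the 90th percentile of protected counts held 52.8% to 64.4% of these counts in the sea urchin and lancelet libraries and 28.0% in zebrafish. Windows with many CpGs or high coverage enter this set by size, so that these shares do not measure how unevenly the level is spread. Levels of neighbouring CpGs were related up to several kb in the sea urchin, with r = 0.444 at 1 to 50 bp and 0.183 at 5 to 10 kb, and in the lancelet, with 0.412 and 0.197. In zebrafish r was 0.394 and 0.0313 at these distances. Counts were summed over 8 sea urchin and 6 lancelet libraries, but zebrafish had 1 library with a median coverage of 12. Counting error therefore lowers r most in zebrafish, and the values cannot be compared between species. From the fifth of CpGs with the fewest CpG neighbours within 250 bp to the fifth with the most, mean levels fell and then rose, with 1.25%, 0.722%, 0.637%, 0.674% and 0.761% in the lancelet and 1.35%, 0.986%, 0.982%, 1.12% and 1.76% in the sea urchin. The ratio of the first to the last of these was above 1 in all 6 lancelet libraries and below 1 in all 8 sea urchin libraries, where it came as near as 0.959 in 72 hpf replicate 1. In zebrafish the fifth with the fewest had 3.67% and the fifth with the most 4.56%.

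Of the 243 lancelet windows lower in juveniles, 39 had a called neighbour directly beside them, where 1000 random placements among the tested windows gave a mean of 1.21 and at most 10. The placements drew evenly from all tested windows, whatever their level, and levels were related up to several kb. The excess therefore does not show clustering beyond that of the level itself.

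Background recurred at fixed positions. Between 8 deeply covered libraries, lambda rates per CpG correlated with a mean r of 0.974 (0.959 to 0.984) across 3109 CpGs, and 47 lambda CpGs (1.51%) were above 10% in all 8. On pUC19, positions 550, 555, 1232 and 1241 were above 20% in all 8. Since pUC19 was hydroxymethylated, these shares need not be background.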
